A study of Mus musculus with 4 samples.

How the data were processed

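H3K27me3 was profiled by Cut&Tag, in which a protein A/G-bound Tn5 transposase cuts and tags chromatin around an antibody, in alveolar macrophages sorted from mouse lung. There were 4 libraries, 2 from wild-type and 2 from Suz12 conditional knockout (cKO) bone marrow chimeras, and the labels give them as biological replicates. Each library was made from 100000 cells with 0.5 µg of anti-H3K27me3 antibody and sequenced as paired reads of 36 bp, per the labels' protocols and design text. The groups and replicate numbers were taken from the sample titles.

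The authors deposited 1 table of whole-number counts, with a row for each of 27095 Entrez genes and a column for each library. Per the submitters' processing notes the build was mm10 and the counter featureCounts. The aligner, the handling of duplicate reads and the counting options are not given in the sources used here. The deposited window lengths are in bp and equal, for 11525 genes, the gene span in the GRCm38.p6 reference table plus 6000 bp. Of the mitochondrial windows that would start before the first base, 3 end exactly 3000 bp past the gene, so the windows were read as the whole gene with 3 kb on each side. Strand plays no part in such counts, and a window holds the gene body as well as the promoter. Of 2446 windows lying wholly within other windows, 67.1% had 0 reads in all libraries, against 1.3% of 10808 windows that overlap no other. Reads in an overlap were thus mostly not counted, and the values of genes with overlapping windows are uncertain to the extent of the overlap, which is given for the named genes that have one. Overlaps were taken from the reference positions with 3 kb on each side. They are approximate where the deposited window length differs from these, as for Fgf1, Zfyve9 and Wnt6. Gene symbols and positions came from the reference table of the same build, in which 25204 IDs (93.0%) were found. The other IDs held 1.87% to 1.94% of each library's counts.

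From these counts, CPM (counts scaled to library size) were computed with TMM factors, and CPM per kb by dividing by the window length. Genotypes were compared gene by gene with edgeR 4.0.16 under R 4.3.3 (filterByExpr, estimateDisp, glmQLFit and glmQLFTest, with genotype as the only term), and genes with a Benjamini-Hochberg adjusted p below 0.05 are called gained or lost. Standard errors of log2 fold changes are their size divided by the square root of F. The filter left 16752 genes and removed 10343. Every adjusted p for a gene is from this test unless another is named. On simulated counts with the real means and totals for this comparison (16041 genes run), the test recovered 20.9% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 74.2% of those changed 3-fold, and 3 of its 101 calls were unchanged genes. Changes of 2-fold and below are therefore often missed, and some of 3-fold are too, with 2 libraries per genotype at this depth.

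Gene lists were fixed before the data were examined: Hox clusters; homeobox, paired-box, forkhead, Sox, T-box and Gata developmental regulators; Wnt, Bmp, Fgf and Hedgehog ligands; Cdk inhibitors; alveolar macrophage identity, peritoneal macrophage, Kupffer cell, microglia, macrophage inflammatory and lipid handling genes; PRC2 and PRC1 components with H3K27 demethylases; T and NK, B and plasma, granulocyte and monocyte, dendritic, lung epithelial, endothelial, and fibroblast and muscle genes; neuronal and imprinted genes; clustered protocadherins; olfactory and vomeronasal receptors; and broadly expressed housekeeping genes. Each of the 23 lists was tested two-sided against all other tested genes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance. On simulated data, 2 of 100 random lists had a p below 0.05. The simulated genes varied independently, so this does not check lists whose genes vary together. The number of called members is also given adjusted over the list alone.

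The genes named in the text follow a rule written before the data were examined: the 10 lowest and 10 highest log2 fold changes among called genes with a mean log2 CPM at or above the median and with both cKO values on one side of both wild-type values, leaving out predicted genes, microRNAs and the near-identical olfactory, vomeronasal, Ear, immunoglobulin and T cell receptor families; the 3 members of each list with the lowest p; and always Suz12, Eed, Ezh2, Cdkn2a, Pparg, Gata6 and Hoxa9. The text gives a selection of these. For the share of counts in the most marked genes, windows were ranked by counts per kb in 1 wild-type library and the share of the top 10% was taken in the other wild-type library and in both cKO libraries, then with the wild-type libraries exchanged. Changes by wild-type level used the same exchange, with a pseudocount of 0.5, whose scaling to library size was chosen after seeing the data. Shares were compared with two-sided exact permutation tests in scipy 1.17.1. With 2 libraries against 2, such a test cannot give a p below 0.333.

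Total counts ranged from 2142175 to 3567282 per library. Intervals treat reads as independent and leave out the spread between libraries. Cut&Tag reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. The alternatives tried were library totals alone, DESeq2 size factors, housekeeping scaling and upper-quartile factors; no count filter and a mean of at least 50 counts; a replicate block; robust empirical Bayes; autosomal genes only; leaving out each library; DESeq2 1.42.0; adjusted p thresholds of 0.1 and 0.01; a test against 1.5-fold; other class sizes and rankings for the shares; and, chosen after seeing the data, thinning to the smallest total and TMM factors from the top decile of genes by wild-type counts per kb.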

Results

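The series asked how loss of Suz12, an obligate subunit of the H3K27 methyltransferase complex PRC2, changes the repressive mark H3K27me3 in bone marrow-derived alveolar macrophages, the resident phagocytes of the airspaces. Irradiated Ly5.1 mice had received marrow that was 90% Ly5.2, either wild type or Suz12 cKO, and 10% wild-type Ly5.1. Whether the sort separated Ly5.2 from Ly5.1 cells is not given in the sources used here. The wild-type libraries held 2592297 and 2142175 counts over gene windows and the cKO libraries 3331138 and 3567282, so the cKO mean was 1.46 times the wild-type mean. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.94 between the wild-type libraries and 1.79 between the cKO libraries, and pairs of different genotype differed more, at 3.43 to 3.89. No library was a copy of another. The main component of log2 CPM (50.5% of the variance) separated the genotypes.

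The targeted gene itself carried almost no H3K27me3 in either genotype. The Suz12 window (chromosome 11, gene at 79993106 to 80034123 in mm10) held 8 and 10 counts in the wild-type libraries and 11 and 10 in the cKO libraries, or 3.88 ± 1.12 and 3.05 ± 0.353 CPM of library totals (SD, n = 2 each). It fell below the count filter. The cKO to wild-type ratio was 0.801, with an exact binomial 95% interval of 0.406 to 1.59. The window spans the whole gene, and which part is deleted is not given in the sources used here, so these counts do not check the deletion. Of the other PRC2 core genes, Ezh2, the catalytic subunit, had 5.34 ± 1.52 CPM in wild type and 4.21 ± 1.40 in cKO (adjusted p = 0.80, with 2.6% of its window overlapped), and Eed had 6.27 ± 0.452 and 3.59 ± 0.116 (adjusted p = 0.424).

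Strongly marked genes still carried H3K27me3 in Suz12 cKO macrophages, and the genes called between genotypes were a minority, with gains as well as losses. CPM are shares of each library, so a change of all signal alike would not show in them. The Hox clusters, classical Polycomb targets that set position along the body axis, had a median of 13.3 ± 2.36 CPM per kb in wild type and 13.4 ± 0.529 in cKO (SD, n = 2 each). Hox windows overlap, and reads in overlaps were mostly not counted, so these levels are low: summed over the clusters and scaled to library totals, counts stood at 10.5 and 11.1 CPM per kb of full window but at 22.8 and 24.0 per kb of unshared window. The latter values divide all counts, including any from overlaps, by the unshared length alone, and so may be too high. Fn1, which encodes fibronectin, rose from 6.13 ± 4.28 to 59.4 ± 3.57 CPM, a log2 fold change of 3.32 ± 0.26 (SE, adjusted p = 9.37e-28). Cdkn2b, which encodes a Cdk inhibitor and is a known Polycomb target, fell from 48.9 ± 0.505 to 13.6 ± 2.34 CPM, a log2 fold change of −1.84 ± 0.22 (adjusted p = 3.12e-13). Gata6, the transcription factor of peritoneal macrophages, was strongly marked in both genotypes, at 389 ± 75.9 and 417 ± 31.7 CPM (log2 fold change 0.10, adjusted p = 0.629), but was called as gained without wild-type library 1 (0.32, adjusted p = 0.0264).

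Of 16752 genes tested, 1076 (6.42%) were called, of which 747 gained and 329 lost H3K27me3 in cKO. Gains exceeded 2-fold at 206 genes and 4-fold at 35, and losses exceeded 2-fold at 137. The gained genes had a median of 0.828 CPM per kb in wild type and 1.48 in cKO, and the lost genes 0.587 and 0.282. Of the 1676 genes with the highest mean CPM per kb, 124 gained and 11 lost, 1 of them by more than 2-fold. The central 95% of the log2 fold changes of these 1676 genes ran from −0.27 to 0.52. Among the 8376 genes of lowest mean CPM per kb, 240 gained and 205 lost, 123 and 114 of them by more than 2-fold. The median log2 fold change of these 8376 genes was −0.15. Most losses, and most changes beyond 2-fold in either direction, thus lay at genes of low level. Windows had a median of 46.5 kb for gained genes, 64.5 kb for lost genes and 29.15 kb for all tested genes. All 1076 called genes had non-overlapping genotypes, as did 47.6% of all tested genes, against 33.3% by chance. The balance of gains and losses depended on the scaling: gains made up 69.4% of the calls with TMM factors, 69.8% with DESeq2 size factors, 55.7% with library totals alone, 48.8% with upper-quartile factors and 98.9% with scaling to housekeeping genes, which shifted the median of all genes by 0.47 on the log2 scale. By DESeq2's Wald test 367 genes were called, 322 gained and 45 lost, so gains made up 87.7%. Without cKO library 1 the calls numbered 589 and without cKO library 2 they numbered 426, and losses numbered 207, 172, 185 and 76 without wild-type library 1, wild-type library 2, cKO library 1 and cKO library 2.

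**Figure D1:**
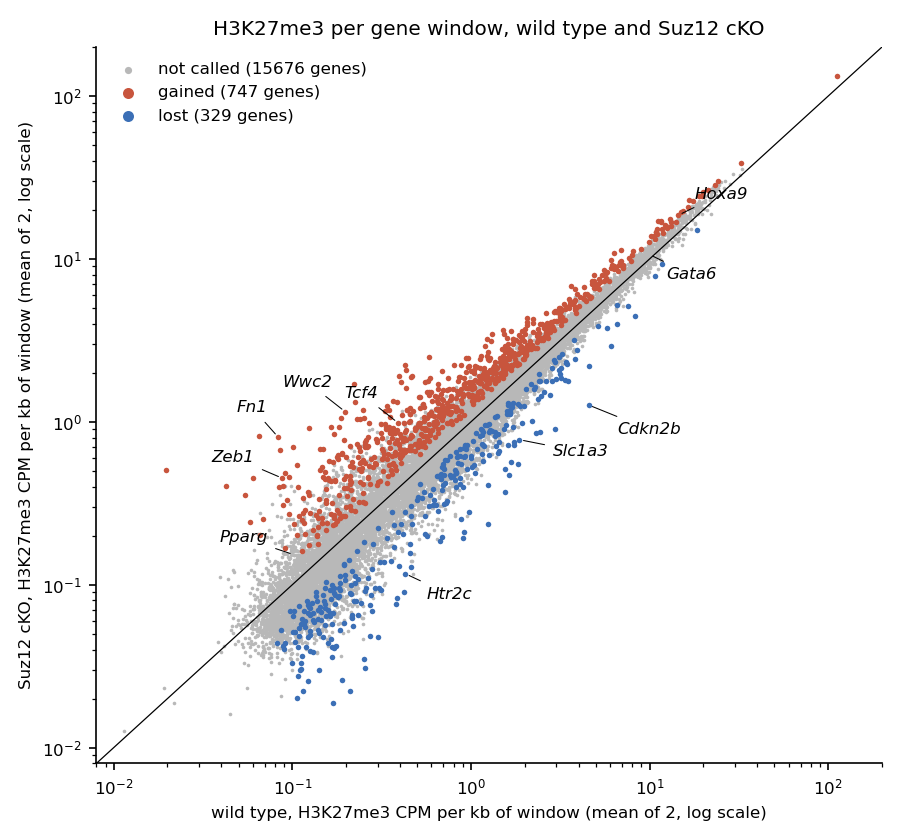
Each point is a tested gene, with its mean H3K27me3 CPM per kb of window in wild type (x) and Suz12 cKO (y), both on log scales, n = 2 libraries each; red genes gained and blue genes lost, and the line marks equal values. Of the 747 gained and 329 lost genes, 240 and 205 lie among the 8376 genes of lowest mean level. Among the 1676 genes of highest mean level, the 124 that gained, such as Hoxa9, lie within 2-fold of the line. All but 1 of the 11 that lost there do so too.

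The 10 genes of largest gain were of varied function. Kdm5b, a histone H3K4 demethylase on chromosome 1 (134560178 to 134632878 in mm10), rose from 14.7 ± 3.20 to 83.5 ± 0.0374 CPM (log2 fold change 2.52 ± 0.19, adjusted p = 1.57e-28). Zbtb10, a zinc finger transcription factor, rose from 9.04 ± 0.169 to 69.8 ± 12.8 CPM. Zeb1, a driver of epithelial to mesenchymal transition, had a log2 fold change of 2.36 ± 0.18, and Cbfa2t3, a transcriptional corepressor of blood development, one of 2.27 ± 0.14 (adjusted p = 1.12e-38). Zfyve9, an adaptor in TGF-β signalling, gained by 2.84 ± 0.20 and Ptch1, the Hedgehog receptor, by 2.28 ± 0.26. Hpgd, which degrades prostaglandins, gained by 2.51 ± 0.31 and Emb, which encodes embigin, by 2.29 ± 0.23. Wwc2, a Hippo pathway regulator on chromosome 8 (47826082 to 47990544), had the lowest adjusted p of all genes (1.67e-46), rising from 33.4 ± 0.0535 to 195 ± 7.19 CPM. Other windows overlap 9.6% of the Kdm5b window, 8.1% of that of Fn1, 4.8% of Zfyve9, 4.5% of Cbfa2t3, 3.7% of Zeb1 and 3.2% of Wwc2, so these values are uncertain to that extent. All 10 of the top gained genes were called under each of the 4 other scalings and without each library.

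The genes of largest loss were likewise varied, and some stood low per kb in wild type. Htr2c, Fgf1, Lepr and Abcc1 had 0.429, 0.459, 0.398 and 0.213 CPM per kb there, below the median of 0.672 over all tested genes. Cdkn2b, Serpinb8, Zfp697, Slc1a3, Fthl17a and Otud7b stood above it, at 4.55, 2.96, 2.31, 1.87, 0.978 and 0.723. Htr2c, a serotonin receptor gene on the X chromosome (146962464 to 147197277), fell from 103 ± 4.69 to 28.1 ± 1.76 CPM (log2 fold change −1.88 ± 0.15, adjusted p = 6.8e-25). Slc1a3, which encodes a glutamate transporter, fell from 154 ± 1.49 to 64.2 ± 0.874 CPM, and Lepr, the leptin receptor gene, from 41.3 ± 10.2 to 13.6 ± 0.616 CPM. Serpinb8, a serine protease inhibitor gene, had a log2 fold change of −1.72 ± 0.18 and Zfp697, a zinc finger gene, one of −1.44 ± 0.14. Fgf1, a growth factor gene, had one of −1.83 ± 0.24, and Fthl17a, a ferritin-like gene whose family is not among those the naming rule leaves out, one of −1.80 ± 0.29. By reference positions the Fgf1 window lies wholly within others, though it held 101 and 87 counts in wild type and 37 in each cKO library. Fthl17a has close copies, so the values of both genes are uncertain. To a lesser extent so are those of Htr2c and Otud7b, of whose windows 13.2% and 8.3% overlap others. Otud7b, a deubiquitinase gene (−1.19 ± 0.20), and Abcc1, an efflux transporter gene (−1.30 ± 0.28), were not called with housekeeping scaling (adjusted p = 0.0845 and 0.0712), and Abcc1 was not called without cKO library 2 (adjusted p = 0.137) or by DESeq2 (adjusted p = 0.0739).

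**Figure D2:**
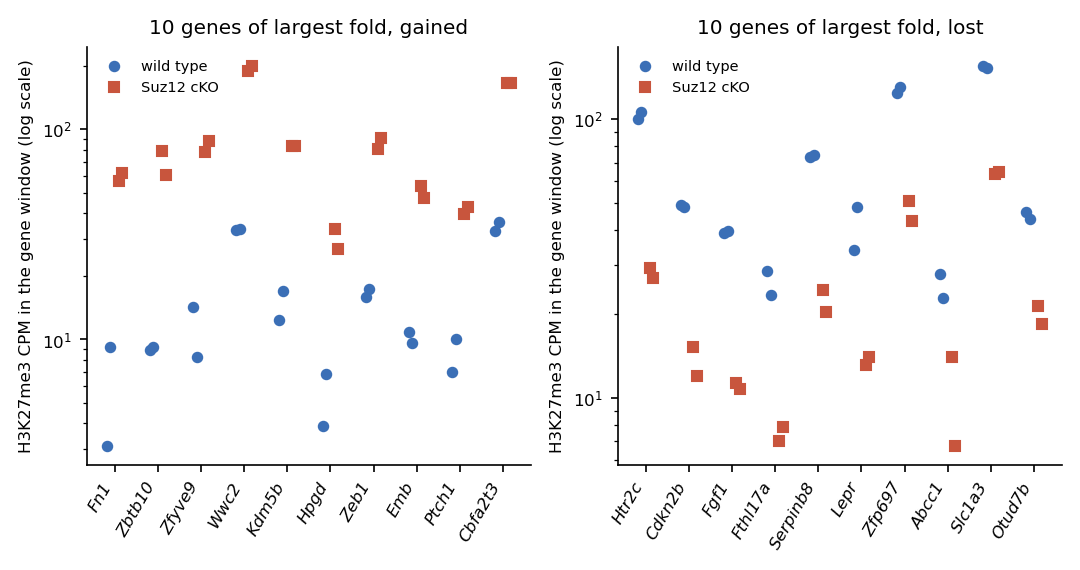
H3K27me3 CPM in the gene window on a log scale for the 10 genes of largest fold in each direction, with 1 point per library (circles, wild type; squares, Suz12 cKO). Both cKO points lie above both wild-type points for the gained genes, from Fn1 to Cbfa2t3, and below them for the lost genes, from Htr2c to Otud7b.

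Gene lists showed where the mark stood and how far it moved. With the preset correlation 8 of 23 lists were called by camera, with an estimated correlation 0 of 23, and by fry's directional test 1, the peritoneal macrophage genes (adjusted p = 0.00178). Among the 8, the estimated correlation was 0.78 for Hox clusters, 0.634 for developmental regulators and 0.337 for Cdk inhibitors, and −0.0474 to 0.0931 for the others. With an estimated correlation camera also rests on the few residual degrees of freedom of 4 libraries, so it could hardly call a list. The dendritic list, at an estimated correlation of −0.025, went from an unadjusted camera p of 6.19e-05 to 0.051. The lost calls therefore do not show that correlation between genes removed them. The developmental regulators, mostly transcription factors of embryonic patterning, had a median of 12.2 ± 1.44 CPM per kb in wild type and 13.3 ± 0.318 in cKO. Of 140 tested, 10 gained and 1 lost (14 and 1 adjusted over the list alone). Their camera adjusted p was 0.00118 in the direction of gain with a median log2 fold change of 0.10, and the adjusted p = 0.83 with an estimated correlation. Of 32 tested Hox genes, 2 gained and 0 lost (4 and 0 adjusted over the list alone), with a camera adjusted p of 0.0143, and adjusted p = 0.83 with an estimated correlation. Hoxa13, of the distal limb, gained by 0.46 ± 0.11 on the log2 scale (adjusted p = 0.00175) and Hoxa9, of blood progenitors, by 0.35 ± 0.11 (adjusted p = 0.0389), the latter in a window that overlaps its neighbours. Without wild-type library 2 neither list was called (camera adjusted p = 0.831 for both), and the medians were 0.00784 for Hox and −0.00263 for developmental regulators. Both lists also lost their calls with upper-quartile factors (adjusted p = 0.143 and 0.0881), a mean of at least 50 counts (0.407 for both) and TMM on the top decile (0.124 and 0.0743), and Hox with library totals alone (0.0582) and without cKO library 2 (0.109). Without wild-type library 2, cKO library 1 and cKO library 2, the adjusted p was 0.731, 0.39 and 0.189 for Hoxa9 and 0.0541, 0.077 and 0.0956 for Hoxa13. Hoxa9 was also not called with library totals alone, upper-quartile factors, thinned counts, TMM on the top decile or DESeq2 (adjusted p = 0.0923, 0.191, 0.0558, 0.209 and 0.343). Of 56 Wnt, Bmp, Fgf and Hedgehog ligand genes, 1 gained, Wnt6 (0.36 ± 0.11, adjusted p = 0.0243, with 3.1% of its window overlapped), and 0 were called adjusted over the list alone. Wnt6 was not called with library totals alone (adjusted p = 0.0584), upper-quartile factors (0.116), TMM on the top decile (0.176) or DESeq2 (0.169), nor without wild-type library 2 (0.27), cKO library 1 (0.296) or cKO library 2 (0.206). The ligand list was not called by camera (adjusted p = 0.345), but was without wild-type library 1 (adjusted p = 0.0063).

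**Figure D3:**
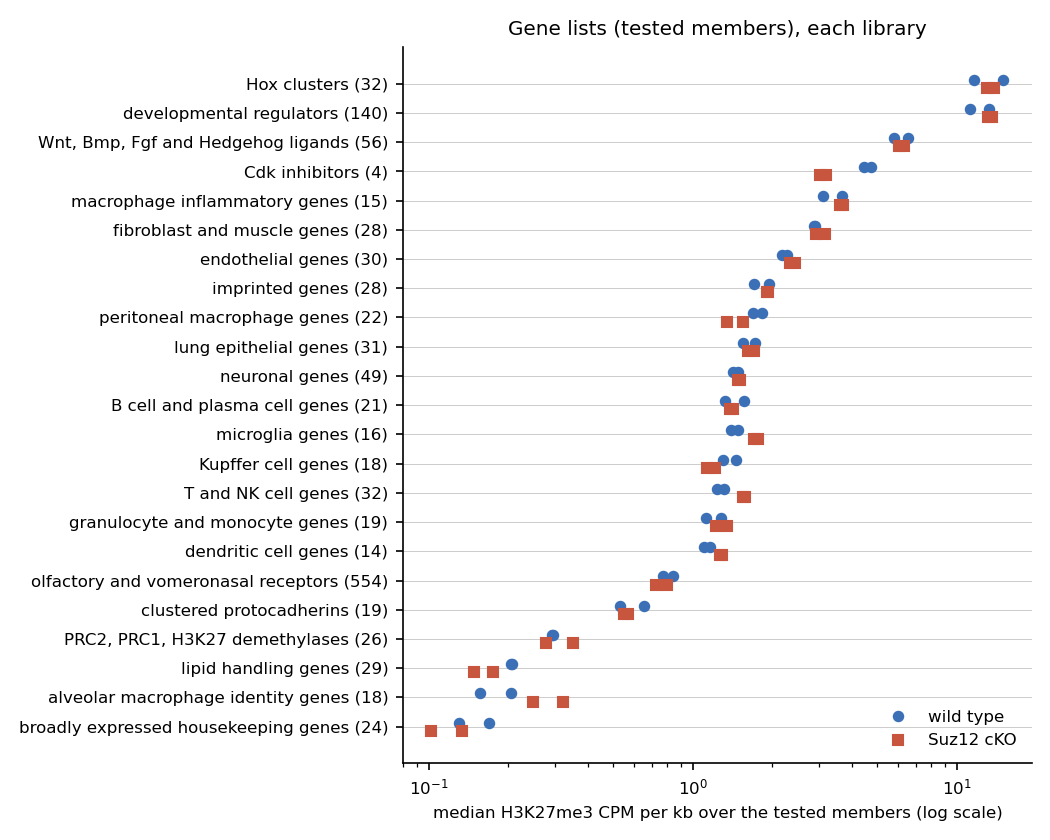
Median H3K27me3 CPM per kb over the tested members of each of the 23 lists on a log scale, with 1 point per library (circles, wild type; squares, Suz12 cKO) and the number of tested members in parentheses. By full window length the Hox clusters and developmental regulators stand highest in every library of both genotypes. Housekeeping genes stand at a median of 0.150 in wild type and 0.118 in cKO. Sums per kb of unshared window were 16.2 and 14.7 for clustered protocadherins, and 9.70 and 10.1 for developmental regulators. Per kb of full window the protocadherin sums were only 0.0259 and 0.0235. Windows wholly shared with others, such as that of Pcdhb19, still hold counts, so the unshared sums cannot rank these lists.

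Of 4 tested Cdk inhibitors, brakes of the cell cycle, 2 lost and 0 gained H3K27me3 in cKO (2 and 0 adjusted over the list alone), and 1 of the others had a positive fold change. The list had a median log2 fold change of −0.47 and a camera adjusted p of 0.00293 for loss, with an adjusted p = 0.58 with an estimated correlation and 0.263 by fry. Next to Cdkn2b on chromosome 4, Cdkn2a, which encodes the tumour suppressors p16INK4A and p19ARF, fell from 306 ± 51.4 to 243 ± 21.4 CPM (log2 fold change −0.34 ± 0.10, adjusted p = 0.0151). The Cdkn2a change was 0.14 with housekeeping scaling (adjusted p = 0.738). The list median was −0.0049 with that scaling. Without wild-type library 1 the list was not called (adjusted p = 0.146, median 0.0237) and Cdkn2a was at −0.15 (adjusted p = 0.564), while Cdkn2b was called under all alternatives run for it. Cdkn2a was also not called without cKO library 1 (adjusted p = 0.0719) or cKO library 2 (adjusted p = 0.537), nor by DESeq2 (adjusted p = 0.242).

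Genes of alveolar macrophage identity carried little H3K27me3 in either genotype, at 0.181 ± 0.0342 CPM per kb in wild type and 0.285 ± 0.0533 in cKO, and none of 18 tested was called (0 adjusted over the list alone, camera adjusted p = 0.245). Without cKO library 2 the list was called in the direction of gain (adjusted p = 0.0352). Pparg, the master regulator of this cell type, had 13.8 ± 3.11 and 20.6 ± 1.51 CPM (log2 fold change 0.59 ± 0.27, adjusted p = 0.208), and was called as gained with housekeeping scaling (1.05, adjusted p = 0.0248). Lipid handling genes stood at 0.206 ± 0.00175 and 0.162 ± 0.0186 CPM per kb. Of 29 tested, 0 gained and 2 lost (0 and 2 adjusted over the list alone), with a camera adjusted p of 0.119, which was 0.0475 without wild-type library 2. Lpcat2, which makes platelet-activating factor, fell from 243 ± 33.5 to 125 ± 4.70 CPM (log2 fold change −0.96 ± 0.11, adjusted p = 1.21e-14), and was at −0.48 with housekeeping scaling (adjusted p = 0.177). Other windows overlap 15.9% of the Lpcat2 window, so its values are uncertain.

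Of 22 tested peritoneal macrophage genes, 3 gained and 1, Vsig4, lost (5 and 2 adjusted over the list alone), with a camera adjusted p of 0.0255 for gain and an adjusted p = 0.58 with an estimated correlation. The list was not called with library totals alone (adjusted p = 0.0542), upper-quartile factors (0.0825), a mean of at least 50 counts (0.239) or TMM on the top decile (0.0743). Besides Fn1, Tgfb2, a TGF-β ligand, rose from 29.6 ± 3.47 to 82.4 ± 5.78 CPM (log2 fold change 1.48 ± 0.16). The list's median CPM per kb was 1.76 ± 0.0942 in wild type and 1.45 ± 0.140 in cKO, opposite in sign to its median log2 fold change of 0.12. Of 16 microglia genes, 4 gained and 0 lost (5 and 0 adjusted over the list alone), with a camera adjusted p of 0.0107 and an adjusted p = 0.58 with an estimated correlation. Bin1, a membrane curvature adaptor, gained by 0.97 ± 0.12 and Sparc, a matricellular protein, by 1.54 ± 0.26. The median of the microglia list was 0.06, and −0.02 with upper-quartile factors and with a mean of at least 50 counts, where it was not called (adjusted p = 0.407). Of 15 macrophage inflammatory genes, 2 gained and 0 lost (2 and 0 adjusted over the list alone), among them Nos2, the inducible nitric oxide synthase (0.39 ± 0.10, adjusted p = 0.00506), which was not called without cKO library 1 (adjusted p = 0.279) or with TMM on the top decile (adjusted p = 0.0929). That list had a camera adjusted p of 0.0341, an adjusted p = 0.688 with an estimated correlation, and an adjusted p of 0.587, 0.225 and 0.109 without wild-type library 2, cKO library 1 and cKO library 2. It was also not called with library totals alone (adjusted p = 0.0542), upper-quartile factors (0.0825), no count filter (0.207), a mean of at least 50 counts (0.271), thinned counts (0.0732) or TMM on the top decile (0.0743). Of 18 Kupffer cell genes, 0 gained and 1 lost (0 and 1 adjusted over the list alone), which is again Vsig4, a complement receptor gene (−0.75 ± 0.21, adjusted p = 0.0105), with an adjusted p of 0.198, 0.123 and 0.0893 without wild-type library 2, cKO library 1 and cKO library 2, 0.51 with housekeeping scaling and 0.235 by DESeq2. The Kupffer list was not called (camera adjusted p = 0.761, median 0.02, mean −0.09). Other windows overlap 11.8% of the Bin1 window, 7.1% of Nos2 and 4.7% of Vsig4, so these values are uncertain to that extent.

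Genes of the other cell types that a lung sort could hold were marked at 1.14 to 2.89 CPM per kb in wild type. Since the mark is repressive, these levels are not expression. Of 14 dendritic cell genes, 3 gained and 0 lost (5 and 0 adjusted over the list alone), with a camera adjusted p of 0.00118 and an adjusted p = 0.58 with an estimated correlation. Tcf4, the transcription factor of plasmacytoid dendritic cells, rose from 137 ± 9.48 to 344 ± 14.8 CPM (log2 fold change 1.34 ± 0.10, adjusted p = 1.96e-27). The other gains, Clec10a (0.79 ± 0.22) and Zbtb46 (0.43 ± 0.13, with 22.3% of its window overlapped), were not called by DESeq2 (adjusted p = 0.202 and 0.206). Clec10a also lost its call without wild-type library 1, wild-type library 2 or cKO library 1 (log2 fold changes 0.78, 0.81 and 0.62). Zbtb46 lost its call without wild-type library 2, cKO library 1 or cKO library 2 (log2 fold changes 0.34, 0.41 and 0.46). Of 32 T and NK cell genes, 2 gained and 0 lost (2 and 0 adjusted over the list alone): Cd28, a costimulatory receptor (1.02 ± 0.19), and Ctla4, an inhibitory one (1.35 ± 0.25). The B and plasma cell list had 1 gain and 0 losses among 21 (1 and 0 adjusted over the list alone), Bank1, a B cell scaffold protein (0.48 ± 0.10, adjusted p = 0.000237). Among 19 granulocyte and monocyte genes 1 gained and 0 lost (1 and 0 adjusted over the list alone), Ly6c2, a monocyte surface antigen (1.25 ± 0.39, adjusted p = 0.0283), whose adjusted p was 0.0928 to 0.168 without any 1 library, 0.0558 with upper-quartile factors and 0.0754 with TMM on the top decile. Lung epithelial genes had 2 gains and 2 losses among 31 (2 and 3 adjusted over the list alone), with Etv5, an ETS transcription factor, falling from 75.1 ± 4.56 to 37.0 ± 4.72 CPM (log2 fold change −1.02 ± 0.16), and at −0.54 with housekeeping scaling (adjusted p = 0.156). Endothelial genes had 0 gains and 1 loss among 30 (0 and 1 adjusted over the list alone), Emcn (−0.63 ± 0.18, adjusted p = 0.0114). Emcn was not called with housekeeping scaling (adjusted p = 0.714) or by DESeq2 (adjusted p = 0.251). Its call was also lost without wild-type library 2, cKO library 1 or cKO library 2 (log2 fold changes −0.53, −0.56 and −0.70). Fibroblast and muscle genes had 2 gains and 0 losses among 28 (2 and 0 adjusted over the list alone). Pdgfrb, a growth factor receptor, gained by 0.47 ± 0.11, and was not called without cKO library 2 (log2 fold change 0.41). Camera called none of these 6 lists (adjusted p = 0.283 for T and NK, 0.397 for B and plasma, 0.775 for granulocyte and monocyte, 0.537 for epithelial, 0.503 for endothelial and 0.621 for fibroblast genes).

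Broadly expressed housekeeping genes, such as those for actin and proteasome subunits, stood at 0.150 ± 0.0280 CPM per kb in wild type and 0.118 ± 0.0221 in cKO. None of 24 tested was called (0 adjusted over the list alone), while their median log2 fold change was −0.60 and the camera adjusted p 0.0107, with an adjusted p = 0.58 with an estimated correlation. The call was lost with upper-quartile factors (adjusted p = 0.0652) and when counts were thinned to the smallest total, a setting chosen after seeing the data (adjusted p = 0.116). Of 26 genes for PRC2, PRC1 and H3K27 demethylases, 2 gained and 0 lost (2 and 0 adjusted over the list alone): Phc2 (0.85 ± 0.13) and Scmh1 (1.27 ± 0.23, with 3.2% of its window overlapped), both PRC1 members. Camera did not call that list (adjusted p = 0.887, direction of gain, median −0.17 and mean −0.08). Of 49 neuronal genes 3 gained and of 28 imprinted genes 3 gained, with 0 losses in either (the same counts adjusted over the list alone), and camera adjusted p values of 0.659 and 0.0847. None of these gains was called by DESeq2 (adjusted p = 0.0791 to 0.365). The imprinted list was called without wild-type library 1 (adjusted p = 0.0117) and with no count filter (adjusted p = 0.0247). None of 19 clustered protocadherin genes, most of whose windows overlap, was called (0 adjusted over the list alone, camera adjusted p = 0.632). Of 554 olfactory and vomeronasal receptor genes, which are near-identical families and so uncertain, 2 gained and 6 lost (2 and 2 adjusted over the list alone, camera adjusted p = 0.345, and 0.0215 with a mean of at least 50 counts). With housekeeping scaling, which adds 0.47 to the median gene, the ligand, T and NK, neuronal, imprinted and olfactory lists were called too (adjusted p = 0.00199, 0.0227, 0.00701, 0.0155 and 0.00496).

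The share of H3K27me3 counts in the most marked genes differed between genotypes by less than the spread between libraries. The top 10% of windows, 2710 genes ranked on the other wild-type library, held 42.5% of counts in wild-type library 1 and 40.0% in wild-type library 2. The cKO libraries held 42.5% and 42.4% when ranked on wild-type library 1, and 42.0% and 41.9% when ranked on wild-type library 2. The mean difference, cKO minus wild type, was 0.991 percentage points with an SD of 1.74 over the 4 differences. Ranked on all libraries, the shares were 41.2 ± 2.12% in wild type and 42.5 ± 0.0900% in cKO (exact permutation p = 1.00). With 2 libraries against 2, the smallest p is 0.333.

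By wild-type level, scaled counts were not lower in cKO where wild type had more H3K27me3. In the highest decile the median log2 ratio of cKO to wild type was 0.18 against wild-type library 2 and 0.01 against wild-type library 1, with a mean of 0.10 and an SD of 0.10 over the 4 library pairs. Deciles 5 to 9 had means from 0.01 to 0.04. In the lowest decile the mean was −0.41, and it was −0.29 in the next, where windows hold few counts per kb. Why the ratio was lower there was not tested. With housekeeping scaling the mean of the highest decile was 0.56. No test was made across genes.

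**Figure D4:**
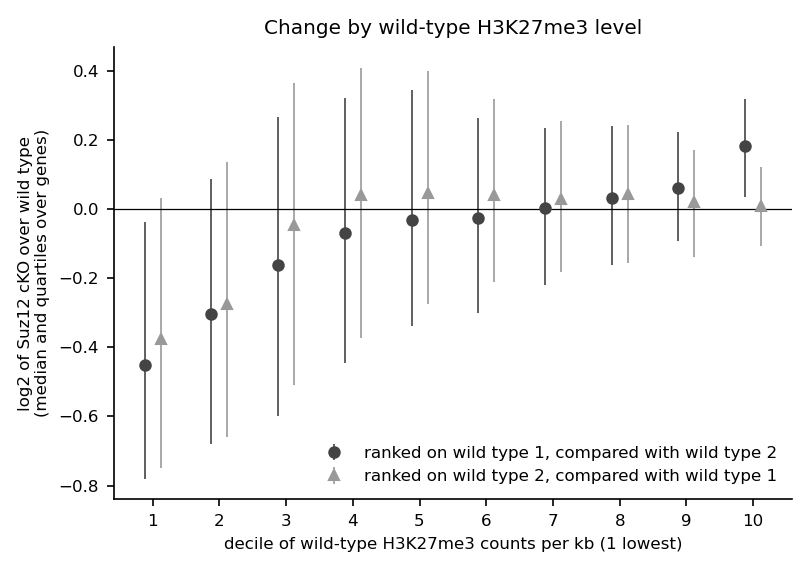
Median log2 ratio of Suz12 cKO over wild type (y) by decile of wild-type H3K27me3 counts per kb (x), with bars from the lower to the upper quartile of genes; circles are ranked on wild-type library 1 and compared with library 2, triangles the reverse. The means of both run from −0.41 in decile 1 to 0.10 in decile 10.

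The X chromosome held 5.38 ± 0.166% of counts in wild type and 5.39 ± 0.0525% in cKO (SD, n = 2 each, exact permutation p = 1.00), and 12 X-linked genes gained while 18 lost. The ratio of cKO to wild-type share ran from 0.978 on chromosome 17 to 1.02 on chromosome 8 over the 19 autosomes. The Y chromosome held 0.00274 ± 0.000280% and 0.00251 ± 0.000220% of counts (exact permutation p = 0.667), or 63 to 89 counts per library.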

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

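Thinning to the smallest total and TMM factors from the most marked decile were chosen after seeing the data; the other alternatives were fixed before. Calls numbered 1076 (747 gained, 329 lost) and lists 8. With housekeeping scaling there were 1856 calls (1835 gained, 21 lost) and 13 lists, and the highest decile stood at 0.56, as that scaling adds 0.47 to the median gene. Upper-quartile factors gave 494 gains, 519 losses and 3 lists, library totals alone 5 lists, TMM on the top decile 392 gains and 4 lists, and a mean of at least 50 counts 3 lists. Adjusted p thresholds of 0.1 gave 548 losses and of 0.01 gave 598 calls (473 gained, 125 lost), a test against 1.5-fold 119 (99 gained, 20 lost), and the DESeq2 Wald test 367 (322 gained, 45 lost), all of them among the 1076; DESeq2 gave no adjusted p for 17342 genes. For lists, an estimated correlation, which leaves camera few degrees of freedom here, gave 0 and fry 1. Leaving out each library in turn, where the lone library is assumed to vary like the others, gave 426 to 945 calls, 350 to 738 gains, 76 to 207 losses and 6 to 9 lists. With the replicate block the calls were 1039 (733 gained, 306 lost) with 8 lists. Deviations of same-numbered libraries had a correlation of 0.00844 across genes. No shared effect of the numbers was thus seen, but counting noise lowers such a correlation, so a shared effect is not excluded. Cdkn2a went from −0.34 to 0.14 with housekeeping scaling, by that scaling's own shift. Without wild-type library 2 the medians of the Hox and developmental lists were 0.00784 and −0.00263, with camera's direction reversed, and without wild-type library 1 they were 0.285 and 0.237; the cause was not tested there or for other changed lists. Of 60 called named genes, 28 were called under all alternatives that tested them and 31 without each library; the call was lost for 12, 17, 25 and 24 without wild-type library 1, wild-type library 2, cKO library 1 and cKO library 2. The difference in the most marked genes' share was 0.276 to 2.50 points in other settings, except −0.515 when ranked on wild-type library 2, within its SD of 1.74, and the X share difference ran from −0.108 to 0.126 points. Small changes are often missed with 2 libraries per genotype at this depth: simulated 1.5-fold changes were recovered in 20.9% of cases.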

Other observations

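The tests of the ratios to mitochondrial and housekeeping counts, the Suz12 window, the scalings, the calls without wild-type library 2 and the other splits were chosen after the results were seen, as were the thinning of counts and the length-matched, 10 kb and abundance-class comparisons; the tests on the density of gained genes and on neighbouring genes were written before.

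Gained genes lay next to each other on the chromosomes more often than shuffled calls. Of gained genes with a known position, 11.8% had a gained gene as the next tested one, against a median of 4.41% and a highest value of 7.55% in 1000 shuffles. Cd28 and Ctla4, neighbours on chromosome 1 at 60746388 and 60909025, were such a pair. For lost genes the share was 7.79%, against a highest shuffle of 4.98%. Among neighbours with windows more than 10 kb apart it was 10.3% for gains and 6.81% for losses, against highest values of 8.58% and 5.82% when calls were shuffled within 20 classes of abundance. Most neighbours did not share the call, and those not called had a median log2 fold change of 0.012 next to gained genes (634 genes) and −0.098 next to lost genes (283 genes), medians that leave out the called neighbours and so decide nothing. The hypothesis that some of the changes may extend over domains wider than a gene is consistent with the shares of called neighbours, and reads between genes were not analysed here.

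H3K27me3 stood at 13.3 ± 2.36 CPM per kb of full window at Hox genes in wild type and at 13.4 ± 0.529 in cKO, in cells from which a PRC2 subunit was to be deleted, and retention and a uniform loss hidden by scaling cannot be told apart. The ratio of counts over developmental regulators to those over mitochondrial windows, whose DNA carries no histones, was 346 and 378 in the wild-type libraries and 314 and 245 in the cKO libraries, with a lowest cKO value of 0.675 times the wild-type mean; these rest on 159 to 464 mitochondrial counts in 2 windows and also move with mitochondrial content. The ratio to housekeeping genes, 72.3 and 64.9 in wild type and 89.6 and 117 in cKO, went the other way. A loss at the regulators with housekeeping windows unchanged would have lowered that ratio. A loss that lowers both alike leaves it as it was. Whether the housekeeping counts are mark or background was not tested, so the ratio does not settle whether a uniform loss was hidden. Whether the sorted cells still carried an intact Suz12 cannot be told apart from retention without Suz12: the ratio of Suz12 window reads was 0.801, the counts are few, and the window holds the whole gene. Cells from the 10% wild-type marrow or from the host could contribute, and no value here measures their share; slow loss of the mark in cells that rarely divide stays open too, as untested.

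The excess of gains over losses may come from the choice of scaling, since gains were 69.4% of calls with TMM factors and 48.8% with upper-quartile factors. Greater depth of the cKO libraries is argued against, as gains were 69.9% of the 884 calls when all libraries were thinned to the smallest total. The direction of the balance is therefore open, while single genes of large fold, such as Fn1 and Cdkn2b, were called under every scaling.

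For the gained genes themselves, weaker enrichment in wild-type library 2 is argued against as the whole cause: 67.6% of them were called as gained again without that library. The ratio of their median log2 fold change against wild-type library 1 to that against library 2, 0.989, was taken on genes chosen for the gain and decides nothing. A minor share of another cell type in the cKO sort stays open. The 20 gained genes of highest fold reached 0.0562 of the developmental regulators' median CPM per kb, below the bound of 0.2 set beforehand for such a share, but their windows were longer (median 36.6 against 11.5 kb), which by itself lowers the ratio; against the 90th percentile of windows of like length the median ratio was 0.226. The 4 libraries can be split into 2 and 2 in only 3 ways, too few for a share under 0.05: the real split, 1 of the 3, called 1076 genes and the others at most 0 by edgeR, with 208 and 205 genes at an unadjusted p below 0.05. Each of the other splits puts both genotypes into each group, so any difference between genotypes widens the spread within groups there. The lack of calls in them is therefore no measure of chance. The genotype stays among the open explanations.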
